A study of Mus musculus with 22 samples.

How the data were processed

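The deposited series measured RNA from the anterior neural tube of Folr2-/- mouse embryos on 22 one-colour CodeLink oligonucleotide arrays, 1 sample per array. Per the labels, pregnant dams received 2 intraperitoneal injections, of sodium arsenate at 9.6 mg arsenic per kg, or of water at 10 µL per g of body weight. The injections fell on gestational day (GD) 7 at hour 12 and GD 8 at hour 12. Embryos were taken at GD8:15, GD9:00 and GD9:12, which were 3, 12 and 24 h after the second injection. The labels state that amplified RNA was labelled with biotin and detected with a fluorescent streptavidin. They do not name the scanner software, the background correction or the scaling method.

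The deposited values were linear intensities, rounded to whole numbers and scaled by the authors so that the mean of each array was about 601.6 at GD8:15, 502.1 at GD9:00 and 1004 at GD9:12. The lowest real value in the table was 56, and below it stood only values of 1 or 2. These 838 values, between 16 and 69 per array, were taken as placeholders for spots without a measurement and set to missing. The plan written before the data were examined had not foreseen placeholders, so keeping them as deposited was run as an added alternative. The log2 medians of the arrays differed by up to 1.24. By the rule of the same plan, quantile normalisation of the log2 intensities (limma) therefore replaced the scaling of the authors. A probe was tested when it had values on at least 2 arrays of each group and its mean lay above the lowest 25% of probes. Of the 10500 probes, 7830 passed, 59 having failed on the number of values; 7283 of them carried 1 gene symbol and stood for 7187 genes. No genome coordinates are given, because each value belongs to an array probe and gene symbols were taken from the array annotation.

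The analysis used R 4.3.3 and limma 3.58.1, with figures drawn by Python 3.11.15 and matplotlib 3.10.9. All 22 arrays entered 1 linear model (lmFit) with 6 group means and an empirical Bayes step (eBayes). Contrasts were arsenic minus control at each stage, the unweighted average of these 3 effects, their pairwise differences, an F test of any change of the arsenic effect between stages, and the 3 differences between the control groups. P-values were adjusted by the Benjamini-Hochberg method over the 7830 probes of a contrast, with a threshold of 0.05. The p-values measure the spread between these samples, since the labels do not say whether each array came from a separate dam. Slide series (A, B, C and D) were read from codes in the sample titles, whose meaning the labels do not state.

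Before the data were examined, 28 gene lists were fixed, holding 764 memberships, of which 609 were on the array. Of these lists, 27 had at least 3 measured genes and were tested with camera at its preset inter-gene correlation of 0.01; the metallothionein and metal response list had fewer and was left out. Each list was also tested by camera with an estimated correlation and by fry, and p-values were adjusted over the 27 lists of a contrast. Each gene was represented by its brightest probe. Of 92 genes with 2 tested probes, the median correlation between the probes across arrays was 0.0489, against 0.0068 for random pairs, and 42 pairs lay below 0. A value therefore stands for its probe, and the assignment of single probes to genes stays in doubt. Ribosomal protein genes had a mean log2 intensity of 12.8 against 8.38 for all tested probes, which checked the symbols of that abundant class alone.

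Genes named in the text follow a rule set before the data were examined. Among probes past the threshold with 1 symbol, the 10 with the highest and the 10 with the lowest log2 difference were taken in each arsenic contrast and in the control difference between GD9:12 and GD8:15. Where fewer than 5 passed in a direction, the probes of lowest p in that direction completed 5. The rule also names up to 4 members of each list with the lowest p, the 10 probes of lowest p in the F test, and Folr2. A few further list members are named to describe a list, and Xist and Eif2s3y were chosen after their values were seen.

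The pipeline was tested on simulated data with 200 changed probes in each of 10 simulations. At GD8:15 it recovered 43.1% of 1.5-fold, 68.4% of 2-fold and 94.9% of 4-fold changes, and 5.38% of its calls were false. The corresponding shares were 36.0%, 66.0% and 94.4% at GD9:00 and 39.6%, 66.0% and 92.3% at GD9:12. For the control difference between GD9:12 and GD8:15 they were 37.0%, 67.0% and 93.2%. A list shifted by 0.5 on the log2 scale was called in 10 of 10 simulations, with 1 call of another list over all of them. The simulated probes varied independently, without bands or correlation between genes, so these shares need not hold for the real arrays. The number of arrays limited the precision: the median standard error (SE) of an arsenic difference was 0.184 at GD8:15 and 0.198 at the later stages.

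Alternatives fixed before the data were examined were the scaling of the authors, cyclic loess, no filter on dim probes, a filter at the median, an offset tied to the median intensity before logs, only the groups compared, a trended and robust eBayes, array weights, only the slide series shared by both groups, series as a block term, a threshold of 0.01, the mean over the probes of a gene, ratios of group medians for single genes, Spearman correlation between stages, and leaving out each array in turn. Alternatives added after seeing the data concerned bands of low signal, found along the probe numbers of single arrays. A band was called where the running median over 51 bright probes of the deviation from each probe's median fell below -0.5 on the log2 scale. A planted band of 300 probes had 276 masked, with 33 other values masked. The added settings masked the bands, combined masking with array weights, left out the arrays with over 5% of their probes in bands, applied normexp background correction with an offset of 50, or kept the placeholders; list tests were also added under cyclic loess, shared series and the series block. Single genes outside the model were compared by exact permutation tests, all two-sided.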

Results

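RNA was measured in the anterior neural tube of mouse embryos that lack Folr2, which encodes a membrane protein that binds folate, after their dams had received sodium arsenate or water. The question, as the labels give it, was which genes arsenic changes in the neural tube of these embryos. Controls and arsenic-treated samples numbered 4 and 4 at GD8:15, 4 and 3 at GD9:00, and 3 and 4 at GD9:12. Intensities ran from 56 to 85027, and the median intensity of an array lay between 123 and 291. Within a group, log2 intensities of a pair of arrays correlated across probes with a median r of 0.941 (range 0.844 to 0.977). The median r was 0.942 between arms of a stage and 0.897 between stages.

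Folr2 itself lay at percentile 2.93 of mean intensity and was below the filter. Its mean log2 intensity was 7.05 ± 0.085 (SD, n = 4) in controls and 6.93 ± 0.20 (SD, n = 4) in arsenic arrays at GD8:15, and group means at the later stages lay between 6.85 and 7.15.

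The leading principal components held 23.6% and 22.4% of the variance, and the stages separated on them more than the arms did. Arsenic replicate 3 at GD8:15 and arsenic replicate 3 at GD9:00 lay apart from their groups. Runs of low signal along the probe numbers covered 16.1% of probes on control GD9:00 replicate 2, 13.9% on replicate 1 and 9.79% on replicate 4, and 9.62% on arsenic GD8:15 replicate 4.

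**Figure D1:**
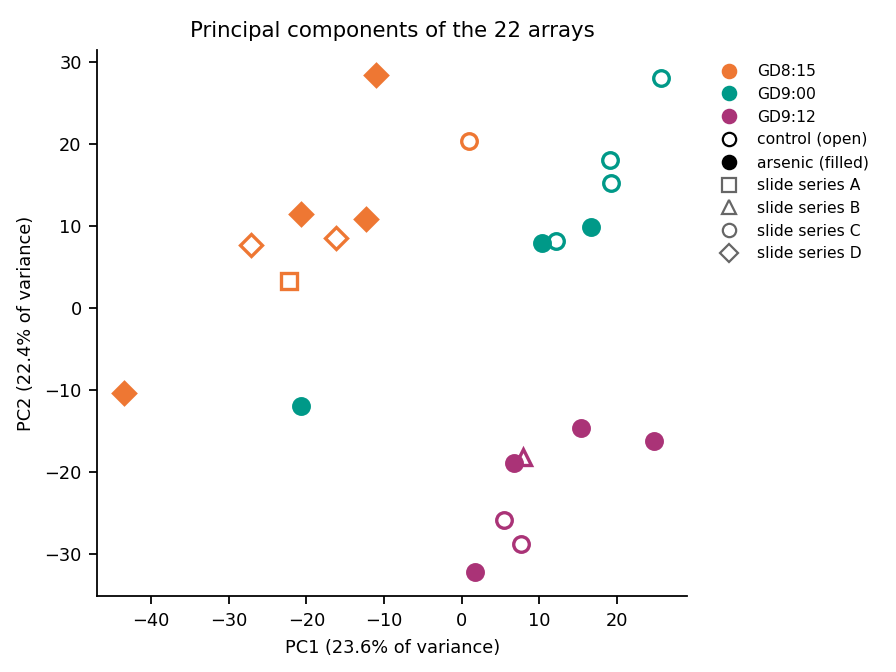
Principal components 1 and 2 of the log2 intensities, with 1 point per array. Of the 7830 tested probes, those with a value on every array were used. Colour gives the stage, open or filled symbols the arm, and symbol shape the slide series. Arsenic replicate 3 at GD8:15 lies at -43.48 on component 1, away from the other arrays of its group.

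**Figure D2:**
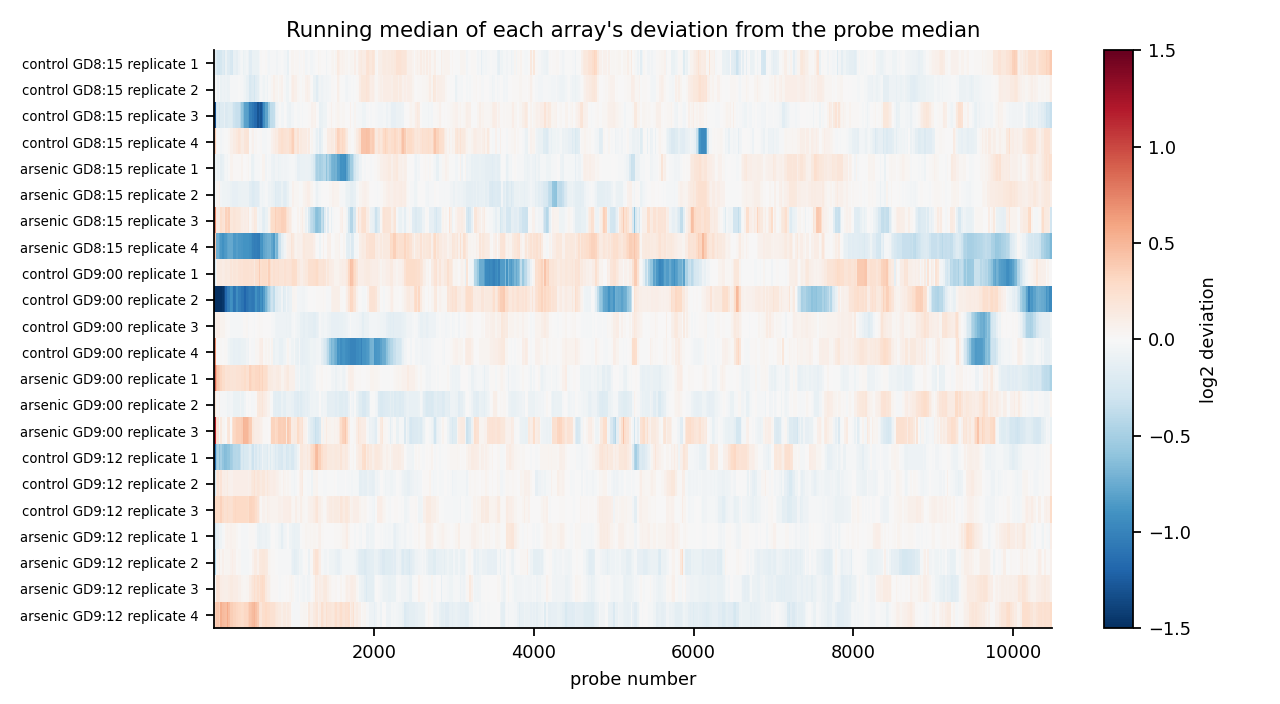
Running median of the deviation of each probe from its median (log2), by probe number (horizontal) and array (vertical, 22 arrays in 6 groups). Blue bands of low signal stand mainly on control arrays of GD9:00, where replicate 2 has 16.1% of its probes in bands.

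At GD8:15, 3 h after the second injection, the list for ER stress and the integrated stress response, through which cells answer amino acid shortage and misfolded protein, rose in the arsenic arrays. It had a median log2 difference of 0.45, with 13 of its 16 measured genes higher (camera adjusted p = 1.8e-05). Chac1, which degrades glutathione and is induced by this pathway, was 2.47-fold higher (log2 1.30 ± 0.22 SE, probe 4836). Atf4, the transcription factor at its centre, stood 1.27 ± 0.31 higher, Atf5 0.74 ± 0.18 and Asns, the asparagine synthetase, 0.96 ± 0.32. Hmox1, which breaks down haem and marks oxidative stress, was 3.43-fold higher, at a mean log2 intensity of 9.43 ± 0.82 (SD, n = 4) against 7.65 ± 0.056 (SD, n = 4) in controls. Control intensities were 134 to 239 for Hmox1 and 142 to 240 for Chac1, near the medians of these arrays (128 to 219). They lay low on the scale, so the size of both fold differences is uncertain.

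The members of this list did not all move one way. Adjusted over the list alone, limma called 4 genes, all higher (Chac1, Atf5, Atf4 and Asns), and 0 over all probes. The chaperones Hspa5 (-0.84 ± 0.38 SE), Sdf2l1 (-0.77 ± 0.43) and Pdia4 (-0.32 ± 0.24), which fold proteins inside the endoplasmic reticulum, had negative differences that did not pass. The call of the list held with an estimated correlation (adjusted p = 0.0123) and with fry (adjusted p = 0.00209). The mean over the list, as the deviation of each gene from its average, was 0.38 ± 0.12 (SD, n = 4) in arsenic arrays and -0.06 ± 0.18 (SD, n = 4) in controls.

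No single probe passed at GD8:15: limma called 0 of 7830 (lowest adjusted p 0.0514), with 571 at an unadjusted p under 0.05 where 391.5 are expected by chance. The genes of lowest p with positive differences were Chac1 and Stc2, a secreted glycoprotein (0.98 ± 0.17 SE, probe 6337), both at a limma adjusted p of 0.0514. They were followed by Slc1a4, a transporter of neutral amino acids (1.09 ± 0.21, adjusted p = 0.0733), Hmox1 (1.78 ± 0.35, adjusted p = 0.0927) and Dph7, needed to make diphthamide on a translation factor (0.59 ± 0.12, adjusted p = 0.0942). The lowest p with negative differences belonged to Pgam2, a muscle form of a glycolytic enzyme (-0.95 ± 0.18), and Sertad1, a transcriptional coregulator (-0.83 ± 0.17). Endou, an endoribonuclease (-0.87 ± 0.21), Obi1, a ubiquitin ligase (-0.65 ± 0.16), and En1, a homeobox gene of the midbrain and hindbrain border (-1.58 ± 0.39), came next. For each of these 10 genes all 4 arsenic arrays lay beyond all 4 controls; a second probe for Obi1 gave -0.16, and with its 1 banded value masked En1 had -1.38.

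**Figure D3:**
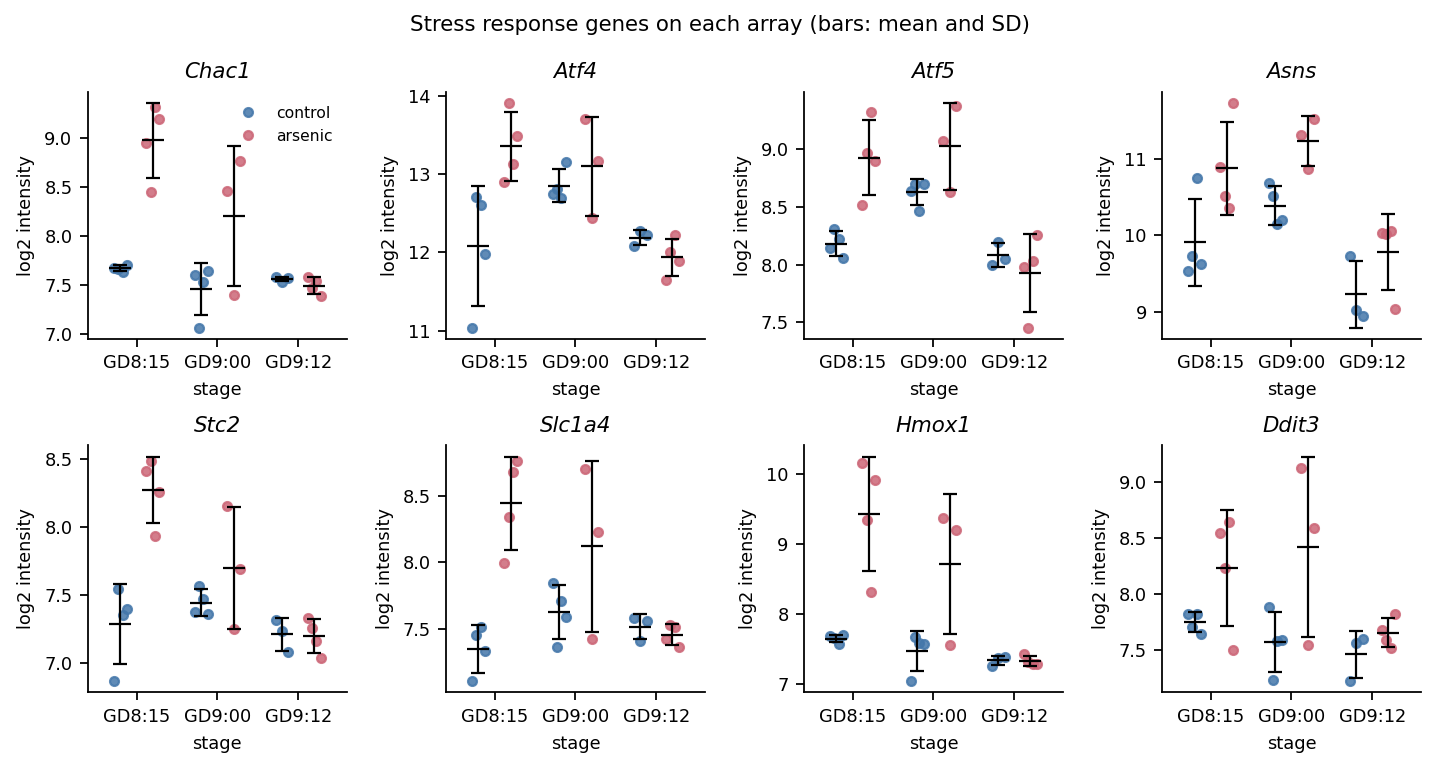
Log2 intensity of 8 stress genes on each array, by stage, for controls (blue) and arsenic (red); bars give the mean and SD. At GD8:15 the 4 arsenic arrays lie above the 4 controls for Chac1, Stc2, Slc1a4 and Hmox1, and at GD9:12 the means of Chac1 are 7.56 in controls and 7.49 in arsenic arrays.

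The heart and muscle list, which marks tissue next to the dissected neural tube, fell at GD8:15 by its mean (-0.37) and median (-0.10), though the median was 0.02 under the scaling of the authors (camera adjusted p = 0.0134; adjusted p = 0.457 with an estimated correlation). Of its 13 genes 3 were higher. The median was -0.21 with bands masked and ran from -0.02 without control replicate 4 to -0.27 without arsenic replicate 2, and the call ended without arsenic replicate 4, a banded array (adjusted p = 0.31, in a range from 0.00138 to 0.31 with an array left out). Adjusted over the list alone, 4 genes fell and over all probes 0: Myl7, the atrial myosin light chain (-1.82 ± 0.52 SE), Actc1, cardiac actin (-1.57 ± 0.53), Nkx2-5 (-0.64 ± 0.23) and Gata6 (-0.55 ± 0.17), both cardiac transcription factors. The scaling of the authors moved the median of all probes by 0.21 at this stage.

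The other 25 lists were not called at GD8:15. In the NRF2 and antioxidant list (20 genes, median 0.05, camera adjusted p = 0.26), Hmox1 alone passed adjusted over the list alone, 0 passing over all probes; Gclm, which makes glutathione, had 0.44 ± 0.19. Adjusted over the list alone, 1 gene passed in each of 4 further lists and 0 over all probes. These were Jund among immediate early genes (1.25 ± 0.35 SE), Ogg1, which removes oxidised guanine, in DNA repair (0.66 ± 0.15), En1 in neural tube patterning, and Hba-x, an embryonic globin, in blood and erythroid (1.07 ± 0.29). The inducible heat shock genes Hspa1a (1.04 ± 0.34) and Hspa1b (1.19 ± 0.43) and Aldh1a2, which makes retinoic acid (1.08 ± 0.36), did not pass. Sox2, a neural progenitor factor, had -0.91 ± 0.31, and Mthfd2, a mitochondrial folate enzyme, 1.55 ± 0.59. With a banded control value masked, the differences were 0.82 for Mthfd2 and 0.57 for Aldh1a2. Median, mean and camera direction did not share 1 sign in the lists for neural tube patterning, neural tube closure, endothelium, neuronal differentiation, Hox genes, DNA repair and surface ectoderm.

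The count of 0 probes became 5 with bands masked or with a trended, robust fit, 4 with array weights, 3 with placeholder values kept, and 3 without arsenic replicate 3. Xist, expressed from the inactive X chromosome of females, was 1.36 higher in the arsenic arrays (exact permutation p = 0.0286, 4 of 4 above all controls), and the Y-linked Eif2s3y was lower by a difference of -0.50 (exact permutation p = 0.0286). Both genes separated the arms in full, so arsenic differences at this stage cannot be told apart from differences of embryo sex.

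**Figure D4:**
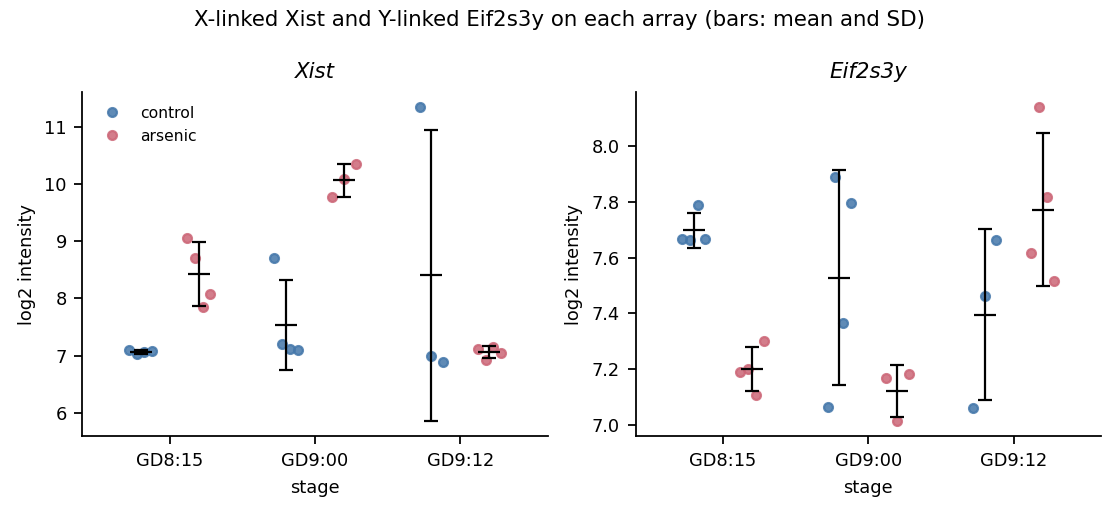
Log2 intensity of Xist and Eif2s3y on each array, by stage, for controls (blue) and arsenic (red), with mean and SD. At GD8:15 and GD9:00 every arsenic array lies above every control for Xist, by 1.36 and 2.53 between the means.

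At GD9:00, 12 h after the second injection, the highest differences of low p included Cdkn1a (log2 1.27 ± 0.26 SE, probe 9557). Cdkn1a encodes the cyclin-dependent kinase inhibitor p21 that p53 induces. Its control mean of 7.105 lay near the 7.03 of Folr2 there, and its probe was banded on 2 control arrays. With those values masked the difference was 1.08, so its size is uncertain. Chst1, a sulfotransferase (3-fold, 1.58 ± 0.32), Pex19, a peroxisome assembly factor (1.40 ± 0.25), Pcp2, a Purkinje cell protein (0.87 ± 0.17), and Gpx2, a glutathione peroxidase (0.52 ± 0.11), stood beside Cdkn1a. Negative differences of low p belonged to Dtnbp1, a protein of lysosome-related vesicles (-0.82 ± 0.16), Med11, a Mediator subunit (-0.79 ± 0.17), and Chn1, a Rac regulator (-0.58 ± 0.12). Fen1, an endonuclease of DNA replication, had -0.56 ± 0.13, and Rapgef1, an exchange factor, -0.32 ± 0.075. For each of these 10 genes the 3 arsenic arrays lay beyond the 4 controls, and none passed: limma called 0 of 7830 probes (lowest adjusted p 0.147), with 984 at an unadjusted p under 0.05, of which 627 were lower.

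The heart and muscle list rose at GD9:00, with 13 of 13 genes higher and a median of 0.30 (camera adjusted p = 0.0261; adjusted p = 0.581 with an estimated correlation). Its members of lowest p were Tagln, a smooth muscle protein (1.65 ± 0.68 SE), Acta2 (0.30 ± 0.15), Tnni1 (0.39 ± 0.22) and Actc1 (1.03 ± 0.57), and 0 passed adjusted over the list alone or over all probes, with limma. With 1 banded control value masked for each, Tagln had 1.06 and Acta2 0.16, and the median of the list was 0.165; it was 0.102 with no filter on dim probes and ran from 0.155 without control replicate 1 to 0.50 without arsenic replicate 2. The oxidative phosphorylation list, subunits of the respiratory chain and ATP synthase, fell by a median of 0.38, with 32 of 42 genes lower (camera adjusted p = 0.0261; adjusted p = 0.774 with an estimated correlation). Sdhd (-0.96 ± 0.32) and Cox7a2 (-0.71 ± 0.27) were among the lower members and Cox6b1 (0.62 ± 0.20) among the higher; 0 passed in limma adjusted over the list alone or over all probes. The scaling of the authors moved the median of all probes by 0.43 at GD9:00, and under it the medians of these lists were 0.63 and -0.44. Without arsenic replicate 3, which lay apart in the principal components, both calls ended, with a median of -0.085 for oxidative phosphorylation (adjusted p = 0.911, in a range from 0.000445 to 0.911 with an array left out) and an adjusted p of 0.295 for heart and muscle (range 0.000291 to 0.295).

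Genes of the integrated stress response had a median difference of 0.38 at GD9:00, 11 of 16 being higher, and the list was not called (camera adjusted p = 0.109). The mean deviation of the list was -0.053 on arsenic replicate 2, among the controls, and 0.367 and 0.207 on replicates 1 and 3. With all arrays, 3 passed in limma adjusted over the list alone and 0 over all probes: Chac1 (0.74 ± 0.24 SE), Ddit3, which encodes the factor CHOP (0.85 ± 0.29), and Shmt2, a mitochondrial serine enzyme (0.60 ± 0.20). In the p53 and apoptosis list (camera adjusted p = 0.29), Cdkn1a passed adjusted over the list alone and 0 over all probes; Phlda3 (1.73 ± 0.60) and Ccng1 (1.44 ± 0.58), both p53 targets, did not. Hspa1b, an inducible heat shock gene (1.69 ± 0.46), passed adjusted over its list alone and 0 did over all probes. The folate and one-carbon list (camera adjusted p = 0.871) had 3 genes past its own adjustment and 0 over all probes: Shmt1 (-0.50 ± 0.12) and Mthfs (-0.54 ± 0.17) lower, Shmt2 higher. Sox17, an endoderm and endothelial factor (0.60 ± 0.18), passed adjusted over the list alone in the endothelium and the endoderm lists, and 0 did over all probes; with its 2 banded control values masked the difference was 0.29.

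The probes of Pex19 and Cdkn1a each lay in low bands on 2 control arrays and those of Pcp2 and Chst1 on 1; with bands masked the differences were 1.09, 1.08, 0.77 and 1.34. The count of 0 became 110 with array weights, 14 without arsenic replicate 2 (10 higher and 4 lower) and 35 without control replicate 2, of which 32 lay in the banded range of probe numbers 9400 to 10000. Xist was 2.53 higher in arsenic arrays at GD9:00 (exact permutation p = 0.0571, 3 of 3 above all controls) and Eif2s3y had -0.41 (exact permutation p = 0.171). At GD9:12 the signs were opposite, with -1.34 for Xist (exact permutation p = 0.4), 1 control lying at 11.34, and 0.38 for Eif2s3y (exact permutation p = 0.143).

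At GD9:12, 24 h after the second injection, Hmox1 and Chac1 stood near their controls. Hmox1 had a mean log2 intensity of 7.32 ± 0.067 (SD, n = 4) in arsenic arrays and 7.33 ± 0.065 (SD, n = 3) in controls, and Chac1 7.49 ± 0.086 and 7.56 ± 0.023 (SD). Asns, the asparagine synthetase, had 0.55 ± 0.35 SE, which did not pass. The differences of lowest p were negative for Il18, a cytokine (-0.74 ± 0.18 SE), Wfdc1, a secreted protein (-1.19 ± 0.33), and Aldh1a1, which makes retinoic acid (-0.39 ± 0.11). Mrps31, a protein of the mitochondrial ribosome, had -0.32 ± 0.095, and 1700037H04Rik -0.52 ± 0.14. Among positive differences were Mphosph10, a ribosome assembly factor (0.89 ± 0.27), Atp5b, an ATP synthase subunit (0.60 ± 0.18), Nosip (0.40 ± 0.12), 5530401J07Rik (0.49 ± 0.16) and 2310076G13Rik (0.40 ± 0.11).

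None of them passed: limma called 0 of 7830 probes at GD9:12 (lowest adjusted p 1), with 100 at an unadjusted p under 0.05, fewer than the 391.5 expected by chance. The model gave each probe 1 spread for all groups. Arrays correlated with the others of their group at a mean r of 0.955 to 0.971 at GD9:12, against 0.894 to 0.946 at GD9:00. Counts at an unadjusted p under 0.05 may therefore be too low at GD9:12 and too high at GD9:00. All 4 arsenic arrays lay beyond the 3 controls for 8 of the 10 genes, and 3 of 4 did for Wfdc1 and Aldh1a1. The proteasome list, subunits of the main protein-degrading complex, rose by a median of 0.17, with 22 of 26 genes higher (camera adjusted p = 0.0485; adjusted p = 0.46 with an estimated correlation). Psma7 (0.57 ± 0.31 SE) and Psmd4 (0.66 ± 0.40) had the lowest p in it, and 0 genes passed adjusted over the list alone or over all probes. Aldh1a1 passed adjusted over the list alone in the retinoic acid list (camera adjusted p = 0.14), and 0 did over all probes. The call of the proteasome list ended under 7 of the 9 other settings run, among them bands masked (adjusted p = 0.0505, in a range from 0.0319 to 0.91), and its median ran from 0.0661 without arsenic replicate 2 to 0.285 without arsenic replicate 4.

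Averaged over the 3 stages, the ER stress and integrated stress response list rose with arsenic (median 0.29, 12 of 16 genes higher, camera adjusted p = 3.88e-06; adjusted p = 0.00723 with an estimated correlation). Adjusted over the list alone, 7 genes rose in limma, and 0 over all probes. They included Chac1 (0.66 ± 0.13 SE), Asns (0.79 ± 0.20), Ddit3 (0.51 ± 0.16) and Atf3, a stress-induced transcription factor (0.62 ± 0.21). Hmox1 had an average difference of 1.00 ± 0.21, Cdkn1a 0.67 ± 0.15, Jdp2, a repressor of AP-1, 1.37 ± 0.33, and Dusp11, an RNA phosphatase, 0.37 ± 0.085. On the negative side stood Mab21l2, a gene of eye development (-0.78 ± 0.18), Rab38, a GTPase of pigment vesicles (-0.51 ± 0.12), Slc22a17 (-0.31 ± 0.079), En1 (-0.90 ± 0.24) and Med11 (-0.34 ± 0.094).

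None of these genes passed for the average effect: limma called 0 of 7830 probes (lowest adjusted p 0.591), with 448 at an unadjusted p under 0.05. Adjusted over the list alone, Hmox1 passed in the NRF2 list, Cdkn1a in the p53 list, and Hspa1b (1.01 ± 0.26 SE) and Hspa1a (0.72 ± 0.21) in the heat shock list, with 0 over all probes in each. Under the scaling of the authors the stress response list was no longer called for the average effect (adjusted p = 0.0724, in a range from 2.09e-07 to 0.0724 over other settings), while its median was 0.33 beside a shift of 0.22 in all probes.

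**Figure D5:**
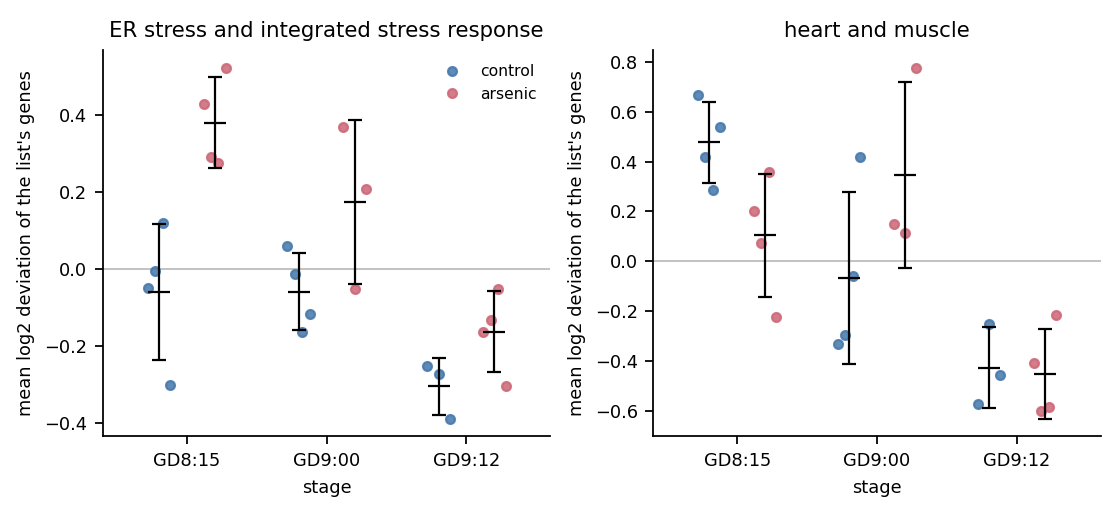
Mean deviation (log2) of the genes of the ER stress and integrated stress response list and of the heart and muscle list on each array, by stage and arm, with group means and SD. At GD8:15 the stress response list averages 0.38 in arsenic arrays and -0.06 in controls; the heart and muscle list averages 0.10 and 0.48, though its median difference is 0.02 under the scaling of the authors.

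Whether the arsenic effect changed between stages was tested directly. The F test of limma called 0 of 7830 probes (lowest adjusted p 0.692), with 503 at an unadjusted p under 0.05. The 10 probes of lowest p belonged to Dtnbp1, Chst1, Cnn1, Bcl6, Pgam2, 1700037H04Rik, Mpdz, Pcp2, Arnt and Dao. Cnn1, a smooth muscle calponin, had means of 9.82 in controls and 8.66 in arsenic arrays at GD8:15, but 8.35 and 9.44 at GD9:00. Arnt, a partner of the hypoxia factors, had 9.00 and 8.75 at GD8:15 and 8.23 and 9.06 at GD9:00. The pairwise differences of the effect also gave 0 calls in limma each, with 639, 500 and 325 probes at an unadjusted p under 0.05 for GD9:00 minus GD8:15, GD9:12 minus GD9:00 and GD9:12 minus GD8:15. The difference of the stress response list between GD9:12 and GD8:15 had a median of -0.34 and was not called (camera adjusted p = 0.0537), so a decline of its response was not shown.

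Across probes, which are not independent replicates, the arsenic effects at GD8:15 and GD9:00 correlated with r = 0.15 (permutation p = 0.62). The values were -0.111 for GD8:15 and GD9:12 (permutation p = 0.54) and -0.156 for GD9:00 and GD9:12 (permutation p = 0.62). The first of these turned to -0.0439 without control GD8:15 replicate 3 and to -0.122 without arsenic GD8:15 replicate 3, and the last to 0.0471 without arsenic GD9:00 replicate 3.

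In controls, the largest changes between GD8:15 and GD9:12 by the naming rule included Zic1 and Wfdc1 among rises and Myl7 among falls. Zic1, a transcription factor of the dorsal neural tube, rose 7.99-fold (log2 3.00 ± 0.25 SE, limma adjusted p = 3.42e-06). Wfdc1 rose 8.38-fold, Fgf18, a growth factor, 5.96-fold (2.57 ± 0.33), and Sox11, a neural progenitor factor, 5.79-fold (2.53 ± 0.42), though a second Sox11 probe gave -0.33. Myl7, the atrial myosin light chain, fell 20.3-fold (-4.35 ± 0.56), Actc1 by 2.76 ± 0.57 and the glycolytic enzyme Ldha by 2.94 ± 0.41 on the log2 scale.

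In all, limma called 604 of 7830 probes between GD8:15 and GD9:12, 295 higher and 309 lower, against 1323 higher and 98 lower under the scaling of the authors. The others among the 10 largest rises were Ccdc88a, an actin-binding protein (2.85), H2az1, a histone variant (2.56), Atp5md (2.45), Peli1, a ubiquitin ligase (2.39), Vbp1, a prefoldin subunit (2.21, with a banded value masked 1.79), and Usp9x, a deubiquitinase (2.19, with -0.18 on a second probe). The others among the 10 largest falls were Trim28, a repressor of transposons (-3.03, with a banded value masked -2.74), Phlda2, an imprinted gene (-2.93), Tkt, of the pentose phosphate pathway (-2.78), Get4 (-2.73), Hspbp1 (-2.73), Ptov1 (-2.72) and Mif, a cytokine (-2.49). In all 20, the 3 arrays of GD9:12 lay beyond the 4 of GD8:15. The heart and muscle list fell by a median of 0.61, 11 of 13 genes being lower, 5 of them called over all probes and 5 adjusted over the list alone (camera adjusted p = 8e-04; adjusted p = 0.359 with an estimated correlation). In the neural tube patterning list (37 genes, camera adjusted p = 0.132), 5 rose and 1 fell over all probes and 5 and 2 adjusted over the list alone. Wnt3a, of the dorsal midline (1.43 ± 0.23 SE), and En2, of the midbrain and hindbrain (1.85 ± 0.35), were among those that rose. In the neural progenitor list (17 genes, camera adjusted p = 0.127), Fabp7, of radial glia, rose by 1.37 ± 0.29 and Sox2 fell by 1.13 ± 0.33, and 2 rose and 1 fell on either adjustment. The scaling of the authors moved the median of all probes by 0.27 here, and under it the median of the heart and muscle list was -0.29; it was -0.23 with series as a block term and -0.25 with no filter on dim probes.

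Between GD8:15 and GD9:00, limma called 1173 probes in controls, 638 higher and 535 lower, against 167 higher and 2578 lower under the scaling of the authors. The oxidative phosphorylation list rose by a median of 0.37, with 32 of 42 genes higher (camera adjusted p = 0.0301; adjusted p = 0.584 with an estimated correlation). With series as a block term the median was 0.21 and the call ended (adjusted p = 0.216, in a range from 4.82e-10 to 0.584 over other settings). Over all probes 6 of its genes rose and 2 fell, and 7 and 2 adjusted over the list alone, Atp5b rising by 1.96 ± 0.17 SE and Cox6a1 falling by 0.86 ± 0.16. The replication gene Mcm5 (0.85 ± 0.12) and the cyclin Ccnd3 (1.14 ± 0.15) rose, as did Pkm, of glycolysis (4.96 ± 0.41), and Isl1, of motor neurons (0.74 ± 0.13). Nefm, a neurofilament subunit, fell by 1.49 ± 0.35, and by 1.37 with a banded value masked. The scaling of the authors moved the median of all probes by -0.49 here, and under it the median of the oxidative phosphorylation list was 0.17.

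Between GD9:00 and GD9:12, limma called 880 probes in controls, 299 higher and 581 lower, a balance that turned to 5498 higher and 103 lower under the scaling of the authors. The glycolysis and hypoxia list fell by a median of 0.70, which turned to a rise of 0.13 under the scaling of the authors (camera adjusted p = 0.00391; adjusted p = 0.238 with an estimated correlation), with Ldha at -3.56 ± 0.41 SE and Pkm at -2.81 ± 0.45. Of its 20 genes 6 fell over all probes, and adjusted over the list alone 9 fell and 1 rose. The proteasome list fell by 0.56, and by 0.916 with bands masked, against a rise of 0.18 under that scaling (camera adjusted p = 0.0056; adjusted p = 0.546 with an estimated correlation), 6 of 26 genes falling over all probes and 8 adjusted over the list alone, among them Psma1 (-2.71 ± 0.53) and Psma7 (-1.83 ± 0.31). The cell cycle and DNA replication list fell by 0.32, against a rise of 0.44 under that scaling (camera adjusted p = 0.0235; adjusted p = 0.546 with an estimated correlation). In it 9 of 33 genes fell and 4 rose over all probes, 13 and 4 adjusted over the list alone; Mcm7 (-1.82 ± 0.24) and Mcm5 (-1.04 ± 0.13) fell and Birc5, of mitosis, rose (1.85 ± 0.38). The scaling of the authors moved the median of all probes by 0.79 here. The globins Hba-a1 (4.15 ± 0.88), Hba-x (1.06 ± 0.31) and Hbb-y (0.90 ± 0.25) rose, and the blood and erythroid list was not called (camera adjusted p = 0.0603). With banded values masked, Hba-a1 had 3.66, Hbb-y 0.79 and Birc5 1.35, and Hba-x, at 1.03, no longer passed (limma adjusted p = 0.0541).

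Slide series and stage were largely confounded in controls, as GD8:15 arrays came from series A, C and D and GD9:00 arrays all from series C. With series as a block term the counts were 35, 519 and 47 in place of 1173, 880 and 604, and of these calls 29, 482 and 36 were shared with the fit without it; Wfdc1, Zic1, Ccdc88a, Fgf18 and Myl7 were the 5 of 20 named genes still called. All 20 named genes kept their sign under the block. Tkt had -1.105 there and H2az1 1.415, well under the values above, and Vbp1 3.74, well over its value. The other named genes moved less, with Ldha at -3.053 and Atp5md at 2.408. None of these 5 values passed.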

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

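Of the tests in this part, the 2 on the positions of the calls made with array weights, the 4 on Xist and the 2 that take the lowest p of any list over the splits were chosen after the results were seen. Masked bands, list tests with shared slide series and the Xist covariate were added after the data had been seen, with predictions written before their results; the others were written before.

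The integrated stress response list rose at GD8:15 and in the average over the stages, with Chac1, Atf5, Atf4 and Asns at its head. No other split of the same arrays gave a camera p as low. At GD8:15 that was 1 of 35 splits (6.65e-07 against 8.32e-05 for the next), and for the average 1 of 100 (1.44e-07 against 0.000128). Taking any of the 27 lists, 1 of 35 splits (7.19e-06 for the next) and 2 of 100 (1.71e-09 in the other) gave a p as low. A chance split is thus unlikely for this list but not excluded, since 1 of 35 is the smallest share that GD8:15 can give. The tables argue against bands of low signal, since with bands masked the camera adjusted p was 7.28e-06 at GD8:15 and 6.31e-07 for the average. They also argue against slide series, since with only the series shared by both arms the adjusted p was 1.53e-06 and 2.09e-07. At GD8:15 that left 2 controls against 4 arsenic arrays. With the scaling of the authors the camera adjusted p was 0.00114 (median 0.58) at GD8:15 and 0.0724 (median 0.33 against 0.29) for the average. This leaves scaling open for the average alone. With log2 Xist as a covariate the camera adjusted p was 0.000609 at GD8:15 and 0.000473 for the average. This cannot decide on embryo sex, since at GD8:15 the arms and Xist coincide. The covariate draws on the spread of Xist within groups. That spread was largest in controls of GD9:12 (SD 2.54), where 1 array lay at 11.34. A response to arsenic is a hypothesis that stays open, beside embryo sex and differences between dams. The labels do not give the dams, and differences between them were not tested.

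With array weights 110 probes were called at GD9:00 in place of 0. Of these, 51.8% lay at positions where at least 2 control arrays had a band of low signal, which held 2.13% of tested probes, so bands shared by controls may have made many of them, the probes of Pex19 and Cdkn1a lying at such positions. For positions banded on at least 1 control array the share was 76.4% (95% interval 67.3 to 83.9) against 38.1% of tested probes, which leaves open whether single bands account for the rest. With bands masked and array weights together limma called 0 probes at GD9:00. An effect of arsenic on the remaining probes stays open.

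Xist, transcribed from the inactive X chromosome, was higher by 1.36 at GD8:15 and by 2.53 at GD9:00 in arsenic arrays, and had -1.34 at GD9:12, where 1 control lay at 11.34 and Eif2s3y had 0.38. At GD8:15 Eif2s3y, on the Y chromosome, was lower in 4 of 4 arsenic arrays (exact permutation p = 0.0286, the smallest these arrays can give), so more female embryos in that arm may account for it. At GD9:00 the exact permutation p of Eif2s3y was 0.171, so this test of the arms did not decide with 3 arrays against 4. Array by array, the arsenic arrays there had Xist at 9.771 to 10.35 and Eif2s3y at 7.015 to 7.181. Control replicate 1 also had high Xist (8.713) and low Eif2s3y (7.063). The other controls had Xist at 7.103 to 7.198 and Eif2s3y at 7.366 to 7.89. High Xist thus went with low Eif2s3y, so embryo sex may account for the difference there too. At GD9:12 the control with Xist at 11.34 also had low Eif2s3y (7.061, against 7.462 and 7.663 in the other controls). Both genes separated the arms in full at GD8:15, and at GD9:00 all arrays but control replicate 1. Arsenic and embryo sex therefore cannot be told apart for any difference at GD8:15, and hardly at GD9:00. Masking decides nothing on bands at either stage. At GD8:15 no Xist value lay in a band, which left 1.36. At GD9:00 the 1 banded Xist value was the highest control, so masking it could only raise the difference, to 2.93. Adjusted over these genes and stages, 0 of the 6 exact permutation tests passed (lowest adjusted p 0.0858). None of these tests could give a p under 0.0286, so several at that floor would have been needed to pass. This result therefore decides nothing on embryo sex. Over all probes, limma called Xist at GD9:00 in 2 of 23 fits, shared slide series (adjusted p = 0.0174) and the series block (0.00868), against 0.245 with all arrays and no block. For the average it did so in 1 of 37, without control GD9:12 replicate 1 (0.0156 against 0.87).

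For probe counts of the arsenic contrasts the real count was 0, which every split reaches by construction, so the splits say nothing on chance: 35 of 35 at GD8:15 (highest other 1), 35 of 35 at GD9:00 (highest other 70), 35 of 35 at GD9:12 (highest other 10), 100 of 100 for the average (highest other 9) and 100 of 100 for the F test (highest other 31). The split with 70 calls at GD9:00 put control replicate 2 with the 3 arsenic arrays, against the other 3 controls. Of its calls 69 had probe numbers from 9400 to 10000, a range with bands on those controls and 5.21% of tested probes, which points to a technical structure of the samples whose cause was not tested. For the number of lists called, chance cannot be excluded either: 15 of 35 splits gave as many at GD8:15 (2, highest other 7), 11 of 35 at GD9:00 (2, highest other 6), 22 of 35 at GD9:12 (1, highest other 8) and 53 of 100 for the average (1, highest other 6). For the developmental probe counts a chance split of the arrays is unlikely, with 1 of 35 splits as large in each. The counts were 1173 against 109 for GD9:00 minus GD8:15, 880 against 366 for GD9:12 minus GD9:00, and 604 against 86 for GD9:12 minus GD8:15. The splits ignore slide series, which is largely confounded with stage. With series as a block term the counts were 35, 519 and 47, while 1168 of 1173, 880 of 880 and 603 of 604 calls kept their sign. Only 1 GD8:15 control came from series C, so the block cannot settle this. Series stays open as a cause of many of these calls. The numbers of lists called there were reached by 11 of 35 splits (1, highest other 3), 6 of 35 (3, highest other 6) and 12 of 35 (1, highest other 4), so chance cannot be excluded.

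In all, 4 list differences between stages passed in camera and not with an estimated correlation. The heart and muscle list had an arsenic effect higher at GD9:00 than at GD8:15 by a median of 0.38, in 13 of 13 genes (camera adjusted p = 0.0001016; adjusted p = 0.539 with an estimated correlation). The oxidative phosphorylation list had an effect higher at GD9:12 than at GD9:00 by 0.42 (adjusted p = 0.002618; adjusted p = 0.657 with an estimated correlation) and than at GD8:15 by 0.19 (adjusted p = 0.01773; adjusted p = 0.582 with an estimated correlation). The Hox list had a median difference of -0.36 between GD9:12 and GD9:00 (adjusted p = 0.0438; adjusted p = 0.657 with an estimated correlation).

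Each named probe was looked at in each group where it had 4 values, which gave 248 cases. In 23 of them (9.27%) 1 array stood apart from the other 3, and 7 of these values lay at banded positions. A rate of about 1 in 20 holds for independent, normally spread values. These probes were mostly named for their differences and share the same arrays, so the 2 rates cannot be compared. In controls of GD8:15 they were 11.72 for En1 (replicate 4), 8.001 for Il18 and 7.79 for Eif2s3y (both replicate 3). In arsenic arrays of GD8:15 they were 9.318 for Dph7 (replicate 1), 8.068 for Mab21l2 (replicate 2), and 8.472 for Mphosph10 and 8.722 for Slc22a17 (replicate 4). In controls of GD9:00 replicate 1 had 7.038 for Hmox1, 8.713 for Xist and 10.81 for Hspbp1, and replicate 2 had 9.172 for Pex19, 7.357 for Peli1 and 9.005 for Tkt. Replicate 3 of the same group had 9.821 for Atp5b and 10.04 for Jdp2, and replicate 4 had 7.14 for Endou, 10.14 for En1, 7.468 for Mrps31 and 9.835 for Mif. In arsenic arrays of GD9:12 replicate 1 had 8.058 for Pex19 and 9.061 for Zic1, and replicate 4 had 8.708 for Phlda2 and 7.433 for Cnn1.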

How the results depend on the processing

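Of the settings below, masked bands, bands masked with array weights, arrays with over 5% of probes in bands left out, normexp, placeholders kept, the list tests under cyclic loess, shared series and series block, and masking and left-out arrays for the correlations between stages were chosen after seeing the data; the others were planned. Why a setting moved a value was not tested unless stated. No paired analysis was possible because replicate numbers follow only the deposition order.

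For probes called with arsenic at GD8:15, in place of 0 limma gave 3 with an offset before logs, 5 with a trended and robust fit, 4 with array weights, 5 with bands masked, 9 with bands masked and array weights, 2 without the banded arrays and 3 with placeholders kept. Leaving out the banded arrays left 1 control at GD9:00, replicate 3, which is assumed to vary like the other groups, so each count without the banded arrays that draws on GD9:00 rests on that lone array. Leaving out 1 array gave 0 to 3, with 1 without arsenic replicate 2 and 3 without arsenic replicate 3. At GD9:00, in place of 0 it gave 1 with the scaling of the authors, 110 with array weights, 1 with shared slide series, 2 with the series block and 32 without the banded arrays (1 control against 3). With 1 array left out it was 0 to 35, with 35 without control replicate 2, 1 without control replicate 4, 14 without arsenic replicate 2 and 1 without arsenic replicate 3. At GD9:12 it gave 1 with array weights and 1 with bands masked and array weights, and 0 to 1 with an array left out (1 without arsenic replicate 4). The average effect gave 2 with the scaling of the authors, 13 with array weights, 19 with bands masked and array weights and 6 without the banded arrays. Single left-out arrays gave 0 to 5, with 5 without arsenic GD9:00 replicate 2 and 1 each without arsenic GD8:15 replicate 3, control GD9:00 replicate 2 or control GD9:12 replicate 1. The F test gave 1 with array weights, 3 without the banded arrays and 0 to 4 with an array left out (4 without control GD9:00 replicate 2, 2 without replicate 4).

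For the developmental change from GD8:15 to GD9:00, the 1173 calls became 382 at a threshold of 0.01, 2745 with the scaling of the authors, 726 with probes above the median, 615 with only the groups compared, 1972 with array weights, 35 with the series block, 2308 with bands masked and array weights and 124 without the banded arrays (1 array at GD9:00). Leaving out 1 array gave 671 to 1394, with 680 without control GD8:15 replicate 1 and 671 without replicate 4. From GD9:00 to GD9:12, 880 became 318 at a threshold of 0.01, 5601 with the scaling of the authors, 1394 with cyclic loess, 1801 with array weights, 516 with shared series, 519 with the series block, 2064 with bands masked and array weights and 91 without the banded arrays (1 array at GD9:00). With 1 array left out it was 402 to 860, with 538, 458 and 402 without control GD9:12 replicate 1, 2 or 3. From GD8:15 to GD9:12, 604 became 240 at a threshold of 0.01, 1421 with the scaling of the authors, 2034 with array weights, 47 with the series block and 2050 with bands masked and array weights. Single left-out arrays gave 290 to 578, with 389 without control GD8:15 replicate 4, and 363, 290 and 312 without control GD9:12 replicate 1, 2 or 3.

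Of 27 lists, 2 were called at GD8:15. This became 1 with an estimated correlation, 1 with fry, and 4 each with the scaling of the authors, shared series and the series block, and ranged from 1 (without arsenic replicate 4) to 4 (without arsenic replicate 3). At GD9:00, 2 became 0 with an estimated correlation, with fry and with no dim filter, 5 with the scaling of the authors and 1 with cyclic loess. Leaving out 1 array gave 0 to 3, with 0 without control replicate 1 or 2 or arsenic replicate 3 and 1 without control replicate 3 or 4. At GD9:12, 1 became 0 with an estimated correlation, fry, cyclic loess, no dim filter and bands masked. With 1 array left out it was 0 to 6, with 3 without control replicate 2, 2 without arsenic replicate 1, 6 without arsenic replicate 4, and 0 without control replicate 3 or arsenic replicate 2 or 3. For the average, 1 became 2 with the scaling of the authors and 4 with bands masked. Single left-out arrays gave 1 to 5, and 15 of the 22 arrays changed it: 5 without arsenic GD9:00 replicate 3; 3 without arsenic GD8:15 replicate 2 or 3, control GD9:00 replicate 3 or arsenic GD9:00 replicate 1; and 2 without control GD8:15 replicate 1 or 3, arsenic GD8:15 replicate 1 or 4, control GD9:00 replicate 2 or 4, arsenic GD9:00 replicate 2, control GD9:12 replicate 1, or arsenic GD9:12 replicate 2 or 3. For GD9:00 minus GD8:15, 1 became 0 with an estimated correlation, bands masked and the series block, 8 with fry and 6 with the scaling of the authors. Leaving out 1 array gave 0 to 2, with 0 without control GD8:15 replicate 1 or GD9:00 replicate 1 and 2 without replicate 2 or 4 of either group. For GD9:12 minus GD9:00, 3 became 0 with an estimated correlation, 8 with fry and 6 with the scaling of the authors, and 2 to 5 with an array left out (5 without control GD9:00 replicate 3 or GD9:12 replicate 2). For GD9:12 minus GD8:15, 1 became 0 with an estimated correlation, 4 with fry, 2 with the scaling of the authors, 3 with cyclic loess and 2 with the series block, and 1 to 2 with an array left out (2 without control GD9:12 replicate 2).

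For single lists the values are adjusted p. The stress response list at GD8:15 was called in 9 of 9 other settings (1.53e-06 to 0.0123) and with each array left out (2.22e-06 to 0.00293). For the average it was called in 8 of 9 (2.09e-07 to 0.0724), the scaling of the authors giving 0.0724, and with each array left out (8.68e-08 to 0.000285). The heart and muscle list at GD8:15 had 0.457 with an estimated correlation and 0.525 with fry, and 0.00138 to 0.31 with an array left out (0.31 without arsenic replicate 4). At GD9:00 it had 0.581 with an estimated correlation, 0.355 with fry, 0.355 with the scaling of the authors, 0.186 with cyclic loess and 0.224 with no dim filter. With 1 array left out it was 0.000291 to 0.295: 0.188, 0.104 and 0.0509 without control replicate 1, 2 or 3 and 0.295 without arsenic replicate 3. The oxidative phosphorylation list at GD9:00 had 0.774 with an estimated correlation, 0.409 with fry, 0.224 with no dim filter and 1.85e-15 with the scaling of the authors. Single left-out arrays gave 0.000445 to 0.911: 0.0792, 0.104 and 0.0851 without control replicate 1, 2 or 4 and 0.911 without arsenic replicate 3. The proteasome list at GD9:12 had 0.46 with an estimated correlation, 0.91 with fry, 0.0578 with cyclic loess, 0.102 with no dim filter, 0.0505 with bands masked, 0.0638 with shared series, 0.0633 with the series block and 0.0319 with the scaling of the authors. Leaving out 1 array gave 0.00177 to 0.305: 0.0555 and 0.301 without control replicate 1 or 3 and 0.305 and 0.146 without arsenic replicate 2 or 3. In controls, the oxidative phosphorylation list from GD8:15 to GD9:00 had 0.584 with an estimated correlation, 0.0568 with fry, 0.062 with bands masked and 0.216 with the series block. With 1 array left out it was 0.0113 to 0.0669: 0.0538 without GD8:15 replicate 1 and 0.0669 without GD9:00 replicate 1. From GD9:00 to GD9:12 the cell cycle list had 0.546 with an estimated correlation, 0.0513 with no dim filter and 0.0734 with bands masked. Single left-out arrays gave 0.0146 to 0.0778: 0.0537 and 0.0778 without GD9:12 replicate 1 or 3. The glycolysis list had 0.238 and the proteasome list 0.546 with an estimated correlation (0.000955 to 0.0098 and 0.00362 to 0.0262 with an array left out), and the heart and muscle list from GD8:15 to GD9:12 had 0.359 (0.000204 to 0.00468).

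The correlation of arsenic effects between GD8:15 and GD9:00 turned to -0.0439 without control GD8:15 replicate 3 and -0.122 without arsenic GD8:15 replicate 3 (range -0.122 to 0.345), and that between GD9:00 and GD9:12 to 0.0471 without arsenic GD9:00 replicate 3 (range -0.272 to 0.0471); between GD8:15 and GD9:12 it ran from -0.136 to -0.0028. Among the named genes of the arsenic contrasts, 573 of 623 values in other settings kept their call and sign, 46 were newly called, 4 uncalled values changed sign and 0 called values did; with an array left out 424 of 440 were kept and 16 newly called. Among named genes of the control difference between GD9:12 and GD8:15, 264 of 280 were kept and 16 lost their call; with an array left out 125 of 140 were kept and 15 lost it. Leaving out values at or below 0 was not run because there were none; only the groups compared was not run for the average and the F test, which need all groups; shared series could not be run for GD9:00 minus GD8:15 or GD9:12 minus GD8:15, where no series had 2 arrays on both sides.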

Other observations

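Of the tests in this part, none was chosen after its result was seen; the lists were fixed before the data were examined, and the 2 hypotheses at the end were written before their tests.

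Several gene groups not described above were not called with arsenic at any stage. The neural crest list, whose cells leave the dorsal neural tube, had camera adjusted p-values of 0.538 at GD8:15, 0.748 at GD9:00 and 0.491 at GD9:12. Neural tube closure genes, whose loss leaves the tube open, had 0.755, 0.72 and 0.986, and neuronal differentiation genes 0.939, 0.871 and 0.111. The Hox list, which patterns the body axis, had 0.939, 0.29 and 0.0828, and the pluripotency list 0.912, 0.571 and 0.827. Arsenic metabolism and transport genes had 0.696, 0.5 and 0.931, and ribosomal protein genes 0.912, 0.969 and 0.986. The mesenchyme list had 0.293, 0.871 and 0.915, and surface ectoderm 0.91, 0.493 and 0.111.

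Single members of these and other groups had large differences that did not pass over all probes with limma. At GD8:15 Pdgfra, a receptor of mesenchyme, had -1.09, Gsto1, which can reduce arsenic species, 0.80, and Rara, a retinoic acid receptor, 1.05. At GD9:00 Jun, an immediate early gene, had 1.59, Zic2 1.14 and Wnt7a 0.93, which were 1.13, 0.78 and 0.77 with banded control values masked. Sox11 had -1.36 there, and 0.04 on a second probe. At GD9:12 Sox10, of neural crest, had 1.06, Egr2, of the hindbrain, 1.19, and Snap25, of synapses, -0.63. Apart from arsenic, genes of such groups that passed over all probes with limma in controls from GD9:00 to GD9:12 included Egr2, which fell by 2.06, Otx2, of the forebrain and midbrain, by 0.97, and Isl1, by 0.95, while Fabp7 rose by 1.18.

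A hypothesis was that the stress response reaches further ATF4 targets, the aminoacyl-tRNA synthetases and amino acid transporters. The 17 genes of this kind chosen for the test, all outside the fixed lists, had a median of 0.04 at GD8:15, 10 being higher, and of 0.04 in the average, 11 being higher. Slc1a4, a transporter also outside the fixed lists, was not among them (1.09 ± 0.21 SE at GD8:15, limma adjusted p = 0.0733). The unadjusted values from camera were 0.135 at GD8:15 and 0.103 for the average, and the camera adjusted p was 0.27 for each. The hypothesis was not borne out by these 17 genes, and these tests cannot exclude it.

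Another hypothesis was that arsenic delays development, which would set its effect against the change that controls go through. Across probes, the correlation of the effect with the change between the other 2 control groups was -0.00834 at GD8:15 (permutation p = 1), 0.0782 at GD9:00 (permutation p = 0.257) and 0.265 at GD9:12 (permutation p = 0.371). Negative values were predicted for a delay. That sign assumes that controls kept changing in the same direction over all stages, which was not tested. Pkm and Mcm5 rose in controls from GD8:15 to GD9:00 and fell from GD9:00 to GD9:12. For such genes a delay at GD9:12 would give a positive relation. At GD8:15 a delay would point to an earlier stage that was not measured. These correlations therefore cannot decide on a delay, and neither a delay nor its absence was shown.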
